A study of Homo sapiens with 6 samples.

How the data were processed

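Total RNA of A549 cells was profiled on 6 oligonucleotide arrays, 3 of drug-free control cells and 3 of cells exposed to 50 µM cisplatin, and per the labels biotin-labelled target was made by oligo-dT priming with a T7 promoter. The deposited values are probe set intensities on a linear scale. They range from -512.3 to 9153, and 723 of 52758 values (1.37%) are at or below 0, so a background signal had been subtracted before deposit. The 75th percentiles of the deposited intensity values ran from 191 to 214 over the arrays. The summarisation software, and whether and how the authors scaled the arrays, are not given in the sources used here, and image files were not analysed here. Arrays carry no read depth, and their number limits the precision.

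Values at or below 0 were set to 0, and an offset of 11.8, the 10th percentile of all positive values, was added before taking log2. Because the 75th percentiles spanned 0.15 on that scale, under the limit of 0.3, the arrays were used as deposited. The 47 control probe sets were left out of the tests, and of the other 8746 those with a mean log2 at or above the 25th percentile, 6559 probe sets, were tested. Gene names came from the probe table of the platform, which gave 7840 of the 8746 a single gene symbol, 388 several and 518 none. The Entrez identifiers of 7838 matched the RefSeq annotation of GRCh38.p14, from which current symbols were taken (0 changed) and, for the closing section, gene spans. Tested probe sets with a single symbol stood for 5816 genes, each represented by its brightest probe set.

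Cisplatin was compared with control in limma 3.58.1 under R 4.3.3, with lmFit and eBayes with an intensity trend, two-sided, and Benjamini-Hochberg adjustment over the tested probe sets at 0.05. The fit had 4 residual and 5.54 prior degrees of freedom. Fold changes and standard errors are those of the fit on the log2 scale with the offset, which makes the folds of dim probe sets smaller than the ratios of their mean intensities. Means and SD are of the deposited intensities. An exact test of 3 arrays against 3 cannot go below 0.1, so none was used for single genes. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

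Before the data were examined, 23 gene lists were fixed, of which 22 are described here: nucleotide excision repair, Fanconi anaemia and homologous recombination, mismatch repair, DNA replication and G1/S, mitosis and G2/M, histones, apoptosis regulators, NF-kB and inflammatory cytokines, immediate early genes and MAPK feedback, NRF2 and glutathione, metallothioneins and zinc export, platinum and copper transport, ER stress and ATF4, heat shock proteins, TGF-beta with YAP and matrix, cholesterol and fatty acid synthesis, interferon response, RNA polymerase II and elongation, ribosomal proteins, the respiratory chain, airway and alveolar epithelial identity, and stromal, endothelial and blood cell markers. Of the 23 lists, 22 had 5 or more tested members and were compared with all other genes by camera in limma, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation. With the preset correlation 4 lists were called, 2 up and 2 down, and 2 kept their calls with the estimated correlation; 1 of these, the mitosis list, is described here. Camera compares the mean test statistic of a list with that of all other genes, and the median log2 fold over the tested probe sets was 0.04. The camera direction differed in sign from the median log2 fold of 7 lists, of which 0 were called.

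Genes were named by a rule fixed at the same time. It took the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold with all 3 cisplatin values beyond all 3 control values, or all that passed where fewer did. In each list it took up to 4 members, the 2 past the threshold with the largest change in the direction of the majority and up to 2 in the other, or the 2 with the lowest unadjusted p where 0 passed. It always took CDKN1A, MDM2, GADD45A, GDF15, FAS, BTG2, XPC, DDB2, MYC, ATF3, ERCC1, GAPDH and ACTB where measured, among 14 genes of which 9 had a named tested probe set. BAX, KIF20A, PCNA and PMAIP1 were added after their values were seen.

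The limma and camera steps were tested on simulated data of 6559 probe sets and 6 arrays, with 200 changed probe sets in each of 10 runs. Of 2-fold changes 90.3% and of 1.5-fold changes 41.6% were recovered, and 5.04% of the calls were false. The simulated noise was independent between probe sets, with no structure shared between arrays, so these shares need not hold for the real arrays. Alternatives covered the scaling between arrays, the offset, the filter, the variance prior, the replicate number as a block, leaving out each array, a minimum fold of 1.5, an ordinary test per probe set, an estimated correlation and the mean of all probe sets of a gene. Added after the data were seen were the 3′/5′ ratio of the control probe sets as a covariate, the removal of control 1 and cisplatin 2 together, array quality weights, and the apoptosis list without FAS, TNFRSF10B, BAX and PMAIP1, its members shared with a list not described here.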

Results

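Messenger RNA was measured in A549 cells, an established line of human non-small cell lung cancer, on 6 short-oligonucleotide arrays. On 3 arrays, cisplatin 1 to 3, the cells had spent 1 hour in medium with 50 µM cisplatin, a platinum drug that crosslinks DNA. The 3 control arrays came from cells kept in medium without the drug. All cultures were then kept for 10 hours in drug-free medium, and per the series description the samples came from 3 independent experiments. Each array held 8746 probe sets besides its controls, of which 6559 were bright enough to be tested. The median intensity per array lay between 57.2 and 67.2, and the number of arrays limits the precision of every value.

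The comparison of treated with drug-free cells asked which transcripts differ 10 hours after a short exposure to cisplatin. The largest rise of a named gene was that of CDKN1A, an inhibitor of cyclin-dependent kinases. Its intensity was 257 ± 21.4 in control cells and 1422 ± 48.5 after cisplatin (mean ± SD, n = 3 each), a 5.35-fold rise. FAS, a death receptor, rose 3.94-fold, from 58.2 ± 6.72 to 263.5 ± 19.5. The mitosis list was lower by camera (adjusted p = 4.27e-27 with the preset correlation and 0.0415 with an estimated one). Of its 31 tested genes 2 passed the threshold, of which AURKA, a kinase of the mitotic spindle, fell from 1367 ± 51.2 to 822 ± 56.8. With limma and Benjamini-Hochberg adjustment, 12 named genes rose and 5 fell, and 2 further probe sets that the probe table pairs with no gene also rose.

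On the log2 scale CDKN1A rose by 2.42 (95% interval 2.19 to 2.64, adjusted p = 4.74e-06) and FAS by 1.98 (SE 0.14, adjusted p = 0.000285). PPM1D, a phosphatase of the DNA damage response, rose 2.96-fold, from 147 ± 13.2 to 461 ± 60.8 (adjusted p = 0.00122). GADD45A, a growth arrest gene, rose 2.36-fold, from 81.5 ± 14 to 210.4 ± 47.1 (adjusted p = 0.0333). SESN1, a stress-response sestrin, rose 2.16-fold, from 48.1 ± 0.147 to 118 ± 0.594 (adjusted p = 0.00870). Smaller rises were those of CCNG1, which encodes cyclin G1 (1.71-fold, adjusted p = 0.0294), the death receptor TNFRSF10B (1.61-fold, 0.0239), the oxidoreductase TP53I3 (1.54-fold, 0.0181) and RPS27L, a relative of the ribosomal protein gene RPS27 (1.52-fold, 0.0146). ANKRA2, which encodes an ankyrin repeat protein, rose 1.84-fold, from 100.4 ± 12.3 to 194 ± 14.8 (adjusted p = 0.0357). CDKN1A, FAS, PPM1D and DDB2 passed in all 6 fits without 1 array, ANKRA2 lost its call in each of them, and the other 7 rising genes passed in 1 to 3. MDM2, BTG2 and GDF15 had no tested probe set with a single gene name, so no values are given for them, and whether a probe set without a gene name measures any of them is not known here.

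DDB2 and XPC, which recognise DNA damage at the start of nucleotide excision repair, were the 2 genes of that repair list to rise. DDB2 went from 304 ± 20.0 to 641 ± 39.5 (2.07-fold, log2 1.05, SE 0.11, adjusted p = 0.00320). XPC went from 165 ± 22.4 to 341 ± 15.4 (2.01-fold, log2 1.00, SE 0.13, adjusted p = 0.0149). The other 31 of 33 tested genes did not pass, ERCC1 with a log2 fold of -0.07 among them, and adjusted over the list alone 3 rose, PCNA being the additional gene (log2 0.39). The list had a median log2 fold of 0.04 and an adjusted p of 0.291 by camera. In the Fanconi anaemia and homologous recombination list 0 of 16 tested genes passed in limma, 1 had an unadjusted p under 0.05, and the adjusted p by camera was 0.425. RAD51C had a log2 fold of 0.31 and REV3L 0.55. The mismatch repair list, with 0 of 5 tested genes past adjusted or unadjusted p in limma, had an adjusted p of 0.798 by camera, a median log2 fold of 0.04 and log2 folds of 0.20 for EXO1 and -0.13 for MSH3.

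Of 31 tested genes of mitosis and the G2/M transition, 2 fell and 29 did not pass. Adjusted over the list alone, 13 fell. The median log2 fold was -0.38, with 28 genes lower and 3 higher, and the adjusted p by camera was 4.27e-27 (0.0415 with an estimated correlation). AURKA fell by 0.73 on the log2 scale (SE 0.09, adjusted p = 0.00870). CCNB2, a mitotic cyclin, went from 950.4 ± 5.75 to 612 ± 54.6 and fell by 0.63 on the log2 scale (SE 0.10, adjusted p = 0.0324). AURKA passed in 3 of the 6 fits without 1 array and CCNB2 in 1. KIF20A, a kinesin of cytokinesis, had a log2 fold of -0.57 and an adjusted p of 0.0589. The DNA replication and G1/S list had a median log2 fold of 0.02 over 29 tested genes, of which 0 passed in limma and 6 had an unadjusted p under 0.05, and an adjusted p of 0.372. In that list TYMS, the thymidylate synthase gene, had a log2 fold of 0.20 and the helicase subunit gene MCM3 one of -0.31.

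The apoptosis list rose by camera, with an adjusted p of 0.000160 (0.128 with an estimated correlation) and a median log2 fold of 0.18 over 27 tested genes. FAS and TNFRSF10B were the 2 members to pass over all probe sets, 25 did not pass, and adjusted over the list alone 4 rose, with BAX and PMAIP1 added. BAX, which opens the outer mitochondrial membrane in apoptosis, had a log2 fold of 1.15 and an adjusted p of 0.0816 over all probe sets. Over 21 alternatives the adjusted p of the list ranged from 2.41e-05 to 0.291. The histone list fell by camera (adjusted p = 0.00321), a call also lost with an estimated correlation (adjusted p = 0.128), and over 20 alternatives the value ranged from 0.00262 to 0.128. Of 9 tested histone genes, 0 passed in limma over all probe sets, 2 had an unadjusted p under 0.05, and the same 2 fell adjusted over the list alone, H2BC12 (log2 -0.39) and H2AC6 (log2 -0.55). The median of the list was -0.06 and its mean -0.15 on the log2 scale.

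**Figure D1:**
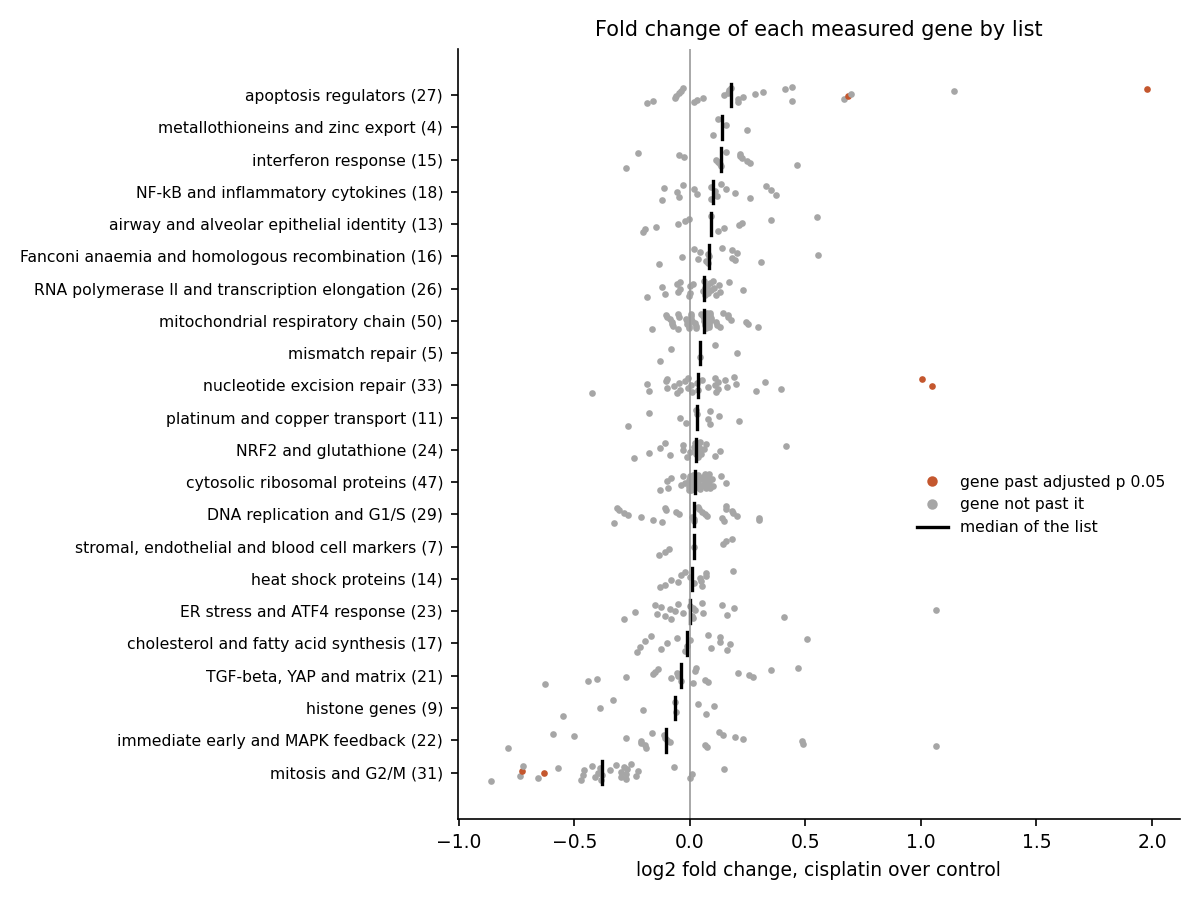
Log2 fold change, cisplatin over control, of each tested gene (points) in 22 gene lists, with the number of tested genes in brackets and a black bar at the median of each list; orange points passed an adjusted p of 0.05 over all probe sets. The median of the mitotic genes lies at -0.38 and that of the apoptosis genes at 0.18.

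Of the probe sets without a gene name, 207813_s_at rose 3.54-fold, from 81.5 ± 7.61 to 320 ± 47.4 (adjusted p = 0.000735), and 201236_s_at rose 2.69-fold, from 155 ± 18 to 437 ± 45.6 (adjusted p = 0.00167). The 3 named genes outside the mitotic list that fell were KCNMA1, DPYD and PRKCA. KCNMA1, a potassium channel gene, went from 165 ± 16.8 to 74.8 ± 11.3 (log2 -1.04, SE 0.15, adjusted p = 0.0276). DPYD, which encodes the first enzyme of pyrimidine breakdown, went from 42.4 ± 0.938 to 12.6 ± 1.34, near the offset of 11.8 added to all values, and its log2 fold was -1.15 (SE 0.17, adjusted p = 0.0304). PRKCA, a protein kinase C gene, went from 901 ± 30.5 to 570.3 ± 56.6 (log2 -0.65, SE 0.10, adjusted p = 0.0343). DPYD and PRKCA lost their calls in each of the 6 fits without 1 array, and KCNMA1 passed in 1 of them. All 3 are long genes, with spans of 768 kb for KCNMA1, 843 kb for DPYD and 508 kb for PRKCA in the RefSeq annotation of GRCh38.p14.

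**Figure D2:**
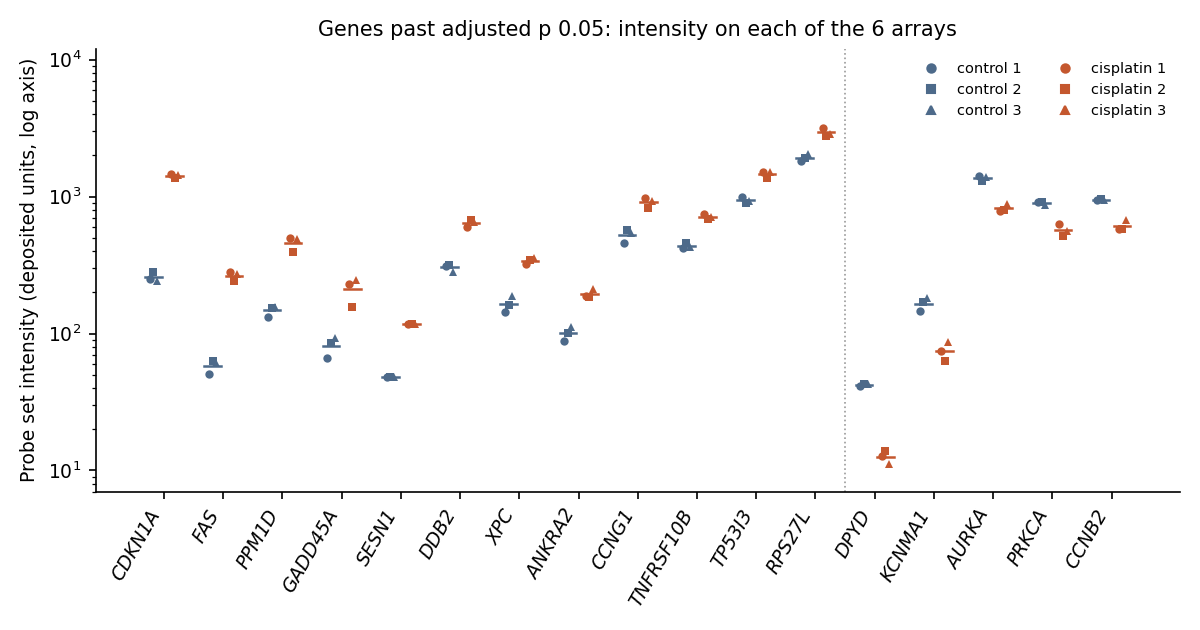
Intensity in deposited units (log axis) of the 17 named genes past an adjusted p of 0.05 on each of the 6 arrays; short lines are group means, and the dotted line parts the 12 genes that rose from the 5 that fell. For each gene the 3 cisplatin arrays lie beyond all 3 control arrays.

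No list of genes that answer other kinds of stress passed camera. The immediate early and MAPK feedback list had a median log2 fold of -0.10 over 22 tested genes and an adjusted p of 0.204, which was 0.0202 without cisplatin 1 and between 0.00775 and 0.934 over 20 alternatives. Of its members 0 passed in limma over all probe sets and 5 had an unadjusted p under 0.05, while adjusted over the list alone ATF3, a stress-induced transcription factor, rose (log2 1.06, 33.4 ± 7.80 to 83.1 ± 19.6) and MYC fell (log2 -0.59, 700.4 ± 25.2 to 464 ± 75.2). Over all probe sets the adjusted p was 0.0976 for ATF3 and 0.193 for MYC. The ER stress and ATF4 list had an adjusted p of 0.425 over 23 tested genes, of which 2 had an unadjusted p under 0.05, with ATF3 the 1 member to pass adjusted over the list alone and TRIB3 at a log2 fold of -0.28. The NRF2 and glutathione list gave 0.798 over 24 tested genes, with log2 folds of 0.11 for TXN and -0.18 for ABCC3. The heat shock list gave 0.504 over 14 tested genes, with 0.19 for HSPA2 and -0.13 for HSP90AB1. Of the metallothioneins, which bind heavy metals, 4 were tested, too few for camera; in limma 0 passed and 1 had an unadjusted p under 0.05. MT1X had a log2 fold of 0.25 and MT2A one of 0.16. The platinum and copper transport list gave an adjusted p of 0.726 over 11 tested genes, with log2 folds of -0.27 for the efflux pump gene ABCC4 and 0.21 for the copper chaperone gene ATOX1.

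In signalling and metabolism the adjusted p by camera was 0.425 for the NF-kB and inflammatory cytokine list (18 tested genes, IL11 at a log2 fold of 0.33 and CXCL1 at 0.35). It was 0.291 for the interferon list (15 genes, IFI44L at 0.46 and IRF1 at 0.26), which had 0.0376 without control 1 and cisplatin 2 together and a range of 0.0376 to 0.849 over 20 alternatives. It was 0.291 for the TGF-beta, YAP and matrix list (21 genes, ID2 at -0.40 and LTBP1 at -0.44). For cholesterol and fatty acid synthesis it was 0.453 (17 genes, SCD at -0.22 and MVD at 0.51). RNA polymerase II and elongation genes gave 0.798 (26 genes, POLR2C at -0.19 and ELOC at 0.12), and respiratory chain genes gave 0.425 (50 genes, NDUFB1 at 0.24 and NDUFA7 at 0.29). The ribosomal protein list gave 0.425 over 47 genes, with RPL30 at 0.09 and FAU at 0.14, and 0.00955 without cisplatin 2, within a range of 0.00955 to 0.945 over 20 alternatives. In each of these 7 lists 0 genes passed in limma, over all probe sets or adjusted over the list alone. At an unadjusted p under 0.05 there were 4 genes in the TGF-beta list, 2 in the cholesterol list, 1 each in the cytokine and interferon lists and 0 in the others.

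Neither list of cell identity markers passed camera. Airway and alveolar epithelial markers had an adjusted p of 0.632 over 13 tested genes, with SFTPB at a log2 fold of 0.55 and AQP3 at 0.35. Markers of stromal, endothelial and blood cells had an adjusted p of 0.798 over 7 tested genes. CD3E had a log2 fold of 0.18 and PECAM1 one of 0.14, with mean intensities of 39.7 to 69.6. The list was fixed as markers that A549 cultures should lack, so intensities of this size need not show expression. The control means of DPYD (42.4) and SESN1 (48.1) lay in the same range. GAPDH had a log2 fold of -0.04 (SE 0.06), within the spread between arrays.

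All 19 probe sets past the threshold had their 3 cisplatin values beyond all 3 control values. Over all 6559 probe sets 721 were separated in that way, or 11% where chance gives 10%. An unadjusted p under 0.05 was found for 330 (223 higher and 107 lower), where 328 would be expected by chance. The arrays were used as deposited, with a median log2 intensity of 6.31 on cisplatin 2 and 6.11 to 6.16 on the others. The median log2 fold of all tested probe sets was 0.04, so the excess of higher ones cannot be told apart from such a shift. The 3′/5′ ratio of the ACTB control probe sets, a measure of RNA integrity, was 2.20, 2.98 and 2.95 on control 1 to 3 and 3.67, 2.67 and 2.94 on cisplatin 1 to 3. Control 1 and cisplatin 2 stood apart from the other arrays on the first principal component. Without both of them 20 probe sets passed, 16 of them among the 19, and 1 mitotic gene was called. The number of calls fell to 6 without control 2, 8 without control 3, 6 without cisplatin 1, 11 without cisplatin 2 and 7 without cisplatin 3. Over the 6 fits without 1 array, 0 to 2 mitotic genes were called.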

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

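The 3′/5′ covariate, the array weights, the removal of control 1 and cisplatin 2 together and the shortened apoptosis list were chosen after the data were seen. The 17 named genes that passed kept their direction in all 304 values under alternative settings, and 202 of these also passed the threshold while 102 did not. CDKN1A, FAS and PPM1D passed under all 18 alternative settings for which values of each gene were kept. The minimum fold of 1.5 and the ordinary test per probe set are not among these, since only counts were kept for them. The mitosis list was called under all 20 alternatives. Against 19 probe sets, 11 passed with arrays centred on the median, 8 without the intensity trend, 4 with a minimum fold of 1.5 and 3 with an ordinary test per probe set, all of them among the 19. With the 3′/5′ covariate 54 passed and with array weights 44, both including the 19; the cause was not tested. Leaving out each array gave 6 to 18 probe sets and 4 to 5 lists, and leaving out control 1 and cisplatin 2 together gave 6 lists, with fewer arrays in the fit. Against 4 lists, 2 were called with an estimated correlation, where the histone and apoptosis lists had an adjusted p of 0.128; without FAS, TNFRSF10B, BAX and PMAIP1, shared with a list not described here, the apoptosis list had 0.291, but these are also its 4 members that rose adjusted over the list alone, so this says nothing about its stability. Leaving out each array gave adjusted p values of 0.00461 to 0.0283 for histones, 3.48e-05 to 0.00295 for apoptosis and 7.85e-30 to 1.77e-17 for mitosis.

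With the replicate number as a block, the replicate block setting, 5 probe sets passed, all among the 19, and the same 4 lists were called. The labels do not say that equal numbers share an experiment. The deviations of arrays with equal numbers from their group means correlated at -0.56, -0.31 and -0.12 across probe sets, and 0 of 6 arrays deviated most like the array of its own number in the other group. The block also uses up residual degrees of freedom, so these lost calls are no measure of the effect.

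Signal over background limits the dim end. DPYD lay near the offset after cisplatin, and its log2 fold ranged from -1.22 to -0.84 over the 16 alternatives that tested it. It fell below the filter without an offset and with the filter at the 50th percentile; without an offset its log2 fold was -1.75, so the offset sets much of its size. The 2187 probe sets below the filter gave 0 calls in limma when it was lifted, among 13 in all, and 122 of them had an unadjusted p under 0.05.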

Other observations

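The RNA integrity test on the calls from another split, the count of splits for the longest genes, the 3′/5′ covariate, the removal of control 1 and cisplatin 2 and the genes named here were chosen after the result was seen. Several genes did not pass the threshold in limma but had all 3 cisplatin arrays on the same side of all 3 controls. Such separation held for 11% of all tested probe sets where chance gives 10%, so it lends these genes no support. SFN, the 14-3-3 sigma gene, was measured by a pair of bright probe sets with log2 folds that were both 0.41 (adjusted p = 0.0589 and 0.0641), from 2853 ± 221 to 3785 ± 142 on the brighter. TIGAR, a regulator of glycolysis, had a log2 fold of 0.90 (adjusted p = 0.104), and TRAF4, a signalling adaptor, 0.80 (adjusted p = 0.174). CYP27A1, a sterol hydroxylase, had 0.79 (adjusted p = 0.0639) and ALDH1A3, which makes retinoic acid, 0.72 (adjusted p = 0.0695). CCNF, a cyclin of the G2 phase, had -0.78 (adjusted p = 0.0768).

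The replication list held genes of the MCM helicase, picked here because they lay on the same side. Of MCM2 to MCM7, 4 had a named tested probe set, and all 4 were lower after cisplatin, with log2 folds of -0.27 for MCM2, -0.31 for MCM3, -0.33 for MCM5 and -0.28 for MCM6. Their median was -0.30, and between -0.35 and -0.28 when each array was left out. In limma 0 of the 4 passed over all probe sets, and MCM2, MCM3, MCM5 and MCM6 had unadjusted p values of 0.132, 0.00955, 0.0105 and 0.0126.

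The 6 arrays allow 10 splits into groups of 3, too few for a share under 0.05. As many probe sets as the 19 of the real split passed in 2 of the 10 splits, the real split included, and the highest of the others had 77. As many lists as the real 4 were called in 5 of the 10 splits, and the highest of the others had 6. The mitosis list was called in 6 of the 9 other splits too, with a median log2 fold of -0.38 in the real split and at most 0.20 in size in the others, which keep part of the treatment difference.

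The split with 77 probe sets set control 1, cisplatin 2 and cisplatin 3 against the other arrays. So many calls with control and cisplatin arrays on each side point to a structure of the arrays apart from the treatment. The split shared 0 of the 77 with the 19, but this lends no support. All 19 had their 3 cisplatin values beyond all 3 control values, so they could hardly pass where the groups are mixed. Dim probe sets were argued against, since 14.3% of the 77 lay below the median intensity, where 50% of all tested probe sets lie. RNA integrity stays open as a candidate explanation, and so does a processing batch, of which the labels say nothing. Over the 6 arrays the first principal component correlated with the mean log2 3′/5′ ratio at r = -0.83 (exact permutation p = 0.0111) and rho = -0.89 (exact permutation p = 0.0333), the 1 relation computed. The r was -0.995 over the 4 arrays left without control 1 and cisplatin 1, of which cisplatin 2 lies apart from the other 3. The 3′/5′ ratio of ACTB was 2.20 to 2.94 on control 1, cisplatin 2 and cisplatin 3 and 2.95 to 3.67 on the others. With the ratio as a covariate, 31 probe sets still passed for that split.

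Of the 5 named genes that fell, KCNMA1, DPYD and PRKCA are among the longest 2% of the tested genes, the 117 with spans of at least 388 kb. Of these 117, 18 were lower at an unadjusted p under 0.05 and 4 higher, so that 15.4% were lower against 1.33% of the other 5699 genes, and SLIT3 (log2 -1.09, adjusted p = 0.0768), GPHN (log2 -0.57), DIAPH2 (log2 -0.64) and NBEA (log2 -0.77) were also in the lower group. The median log2 fold of the 117 lay 0.12 below that of the others. This difference of -0.12 was -0.14 with the 3′/5′ covariate and -0.13 without control 1 and cisplatin 2. The value with the covariate argues against a linear effect of the 3′/5′ ratio as the whole cause. The other argues against control 1 and cisplatin 2 alone as the whole cause. RNA integrity beyond that linear term stays open. Without control 1 and cisplatin 2, control 2 and control 3 still lay opposite cisplatin 3 in the split with 77 probe sets. With each array left out the difference was -0.16 to -0.05. It was smallest, at -0.05, without control 3, so much of it depends on that array, and differences between arrays stay open as a cause. Camera gave p = 2.90e-08, and 0.0211 with an estimated correlation. A lower yield of transcripts from the longest genes in cisplatin-treated cells would need such a fall. This may be such an effect, as a hypothesis found and tested on the same data. The cut at 2% was not planned, and the 117 include KCNMA1, DPYD and PRKCA, so these p values are no independent test. As many of the 117 moved one way in 2 of the 10 splits, too few for a share under 0.05. The highest of the others had 20 against 18, in the split above with 77 probe sets, for which RNA integrity stays open. Those 20 were higher on the side with the higher 3′/5′ ratio, while the mean log2 ratio was 1.37 with cisplatin and 1.24 in controls.

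Over all 5816 genes, each with a span, the log2 fold went with gene length at a Spearman rho of -0.084 across genes, which are not independent replicates, with medians of 0.05 in the 1164 shortest genes and 0.01 in the 1163 longest. The values argue against intensity, since the longest genes lay below the shortest in 5 of 5 intensity bins. They also argue against a linear effect of the 3′/5′ ratio as the whole cause (rho = -0.217 with the covariate). RNA integrity beyond that linear term stays open. Without the genes of the fixed lists rho was -0.0963, which argues against these genes as the cause. A rho as large in size came from 9 of the 10 splits, and 10 splits are too few for a share under 0.05. The highest of the others, at 0.271, was the split of control 1, cisplatin 2 and cisplatin 3 against the other arrays. The trend turned to 0.00151 without control 3 and 0.0123 without cisplatin 2, and it was -0.212 without control 1, -0.171 without cisplatin 1 and -0.0105 without control 2. A lower yield of full-length transcripts cannot be told apart from the differences between arrays, since the 1163 longest genes had a p of 0.00831 by camera and 0.390 with an estimated correlation.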
